A study of Arabidopsis thaliana with 4 samples.

How the data were processed

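Polyadenylated RNA of Arabidopsis thaliana Col and Ler seedlings, 14 days old and grown on plates with 8 h of light and 16 h of dark at 22 °C, was sequenced in 2 samples per ecotype, per the labels. The labels name the first leaf as the source, while their extraction text names shoots. Whether the samples came from separate plantings is not stated. Read strandedness is not given in the sources used here, so events of overlapping or antisense genes may share reads.

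TopHat and the genome build TAIR10 are named in the submitters' processing notes, without versions. The deposited table gives each event a type, an identifier with Col and Ler coordinates, an inclusion level per ecotype and a text cell. The inclusion level is a fraction between 0 and 1, deposited by the authors as 1 value for Col and 1 for Ler, per the file headers. How the samples were combined, which read minimum was used and how the levels were estimated is not given in the sources used here. The text cell holds the authors' q value of the comparison, per the file headers, with a sign for higher in Col, higher in Ler or neither. The test behind the q value, the Ler assembly and the rule for the sign are not given in the sources used here. Tested on the file, every event with a direction sign had q under 0.05 and a difference above 10 percentage points in the authors' deposited table, and 135 further events that met both had none. Read counts and values per sample were not used here, so the depth is unknown.

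Levels were multiplied to percent. Which form the level describes was settled from the values: where only the spliced form of an intron is annotated the median level in Col was 16.8%, and where only the retained form is annotated it was 95.6%. A retention level can be high where a different junction over the same interval is in use, so it is not always the share that keeps the intron. The event table's coordinates were compared with the RefSeq copy of the TAIR10 nuclear chromosomes. Of 7399 introns in retention events 4756 (64.3%) equalled an annotated intron, and 0 did when shifted by 1 bp. Gene names and products came from that annotation, where 5252 of 5268 genes matched. Location compares the alternative segment with the coding span of the gene: a segment before the start codon is on the 5' UTR side even where it is an intron. Of the events, 61 lack a coordinate in one genome.

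The design fixed before the data were examined planned a count test over samples. It did not apply, because the table holds fractions, so the authors' marks were described, as the same design foresaw for a table with a comparison only. P-values below compare classes of events or genes. They hold no information on the spread between samples, and events of 1 gene are not independent. Since the reads behind an event set whether a difference can be marked, classes that differ in depth can differ in their share of marked events. Shares carry 95% Wilson intervals, which cover counting of events only. Contrasts used two-sided Fisher's exact tests with conditional odds ratios, Benjamini-Hochberg adjustment over the levels of a family, two-sided exact binomial and McNemar tests, and exact stratified Cochran-Mantel-Haenszel tests. The classes of interval length, location, step size, annotation, chromosome and junction ends were chosen after the data were seen, and p-values for single contrasts are unadjusted where no adjustment is named. Neighbouring genes, meaning consecutive genes among those with events, were tested one-sided with 10000 shuffles of marks within chromosomes.

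Named events followed a rule fixed beforehand for pooled values: the 10 largest differences in each direction, 1 event per gene within a direction, and up to 4 members of each of 8 gene lists (155 genes) by the same order. The selection of 10 marked events in each direction, and of marked list members, was added after the values were seen, because 7 of the 20 events under the fixed rule carry no mark. The genes with the most events and those with junctions lacking common ends were also chosen after their values were seen. The values of 1 list member that the rule names are not reported here. Since the authors' deposited table gives q values over all events and no p-values, a count adjusted over the list alone was not computed.

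Alternatives tried were q under 0.05 with a difference of at least 10 points, q under 0.05 alone, differences of at least 20 points, 1 event per gene (the first by position), and sets without levels of 0, without lost coordinates or another length in Ler, or without genes within 500 bp of another gene. For levels of 0, events with q under 1 were also counted alone. The tests were tried on simulated marks on the real events. A planted odds ratio of 3 between length classes of 14072 events was recovered with a median of 2.97 over 100 simulations, and was called in 100. With nothing planted, a type was called in 3 of 100. For the SR list of 17 genes a planted odds ratio of 8 was called in 91 of 100, so smaller differences of a list this size can be missed. The stratified test recovered a median of 2.94 for a planted 3 in 50 simulations. The shuffle test called 20 of 20 simulations with planted pairs and 1 of 20 without. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

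For the technical tests in the closing section, the question of annotation was first posed as 1 joint prediction, that the annotated form is higher in Col and that events with both forms annotated show no excess of Col. Its first part held and its second did not, so it was split into separate parts after the result was seen, and the first part was restated for the inclusion level, since the annotated form is often the excluding one. The reading of the test of neighbouring genes was also made stricter after its result was seen: at the ratio of all genes to their shuffles the smaller set would hold 84.6 pairs, which is not above the 86 that bound its shuffles, so its result was read as open. The test of junction ends was read as open after its result was seen, because its outcome was close to fixed. TopHat looks for new junctions at GT-AG, GC-AG or AT-AC ends, and the settings the authors used are not given in the sources used here.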

Results

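Alternative splicing was measured by sequencing of polyadenylated RNA from 14-day-old Arabidopsis thaliana seedlings of the Columbia (Col) and Landsberg erecta (Ler) ecotypes, natural strains that differ in genome sequence. The labels give 2 samples per ecotype, 4 in all. The values analysed were the inclusion levels of 14133 alternative splicing events in 5268 genes, as the authors deposited them, with 1 pooled value per ecotype. The inclusion level stands for the form that keeps the intron, uses the longer exon end or contains the exon. For retention it is not always the share of transcripts that keep the intron, as RABG3d and ZML1 show below, and retention levels are given here as listed. The number of reads behind each level is unknown, and the spread between samples is not shown, so no level below has an SD, an n or an interval of its own. Differences between the ecotypes are those the authors' deposited table marks as higher in Col or in Ler. Each marked event had a q value under 0.05 and a difference of over 10 percentage points in the authors' deposited table.

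The catalogue describes which kinds of alternative splicing occurred in these plants. Intron retention made up 52.4% of the events (7399 events, 95% Wilson interval 51.5 to 53.2%) and occurred in 3762 genes. Alternative 3' splice sites, where the downstream exon starts at one of a pair of acceptor sites, gave 4026 events (28.5%, 27.7 to 29.2%). Alternative 5' splice sites, the same choice at the donor site, gave 2137 events (15.1%, 14.5 to 15.7%), and exon skipping gave 571 (4.04%, 3.73 to 4.38%). With 1 event of each type counted per gene, 8465 remained and retention made up 44.4% of them. The gene with the most events was AT3G18500, with 38 events of which 10 were marked. Next was GRP7, a glycine-rich RNA-binding protein under clock control, with 31 events of which 2 were marked. PnsB4, a subunit of the chloroplast NDH complex, had 29 events and DFD, a folate enzyme, had 27, and none of these was marked.

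Inclusion levels were alike in the ecotypes for most events. The median listed level of retention events was 48.7% in both ecotypes, but it pools unlike classes. In Col the median was 16.8% where only the spliced form is annotated and 38.1% where both forms are. It was 80.5% where neither form is annotated and 95.6% where only the retained form is. The median level of alternative 3' sites was 71.7% in Col and 69.8% in Ler. That of alternative 5' sites was 47.2% and 43.5%, and that of skipped exons 91.8% and 92.0%. Across events, which are not independent replicates, Pearson's r between the ecotypes was 0.909 and Spearman's rho 0.892. The median absolute difference was 3.78 percentage points, and 57.2% of events differed by at most 5 points.

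The comparison of the ecotypes asked how far splicing has diverged between them. The marked events numbered 1054 (7.46% of 14133) and lay in 711 genes. Of these, 577 had the higher inclusion level in Col and 477 in Ler. The share higher in Col, 54.7% (Wilson interval 51.7 to 57.7%), differed from an even split (exact binomial test, two-sided p = 0.00228). Unmarked events leaned the same way, with 6652 of 13020 higher in Col (51.1%, 50.2 to 51.9%), and the marked events exceeded them (odds ratio 1.16, 1.02 to 1.32, Fisher's exact test, exact p = 0.0229). The share was 50.3% (42.4 to 58.3%) of 149 marked events outside genes within 500 bp of another gene (exact binomial p = 1). The median difference of marked events was 21.9 points. It exceeded 50 points in 151 events and 90 points in 49. A q value under 0.05 alone, whatever the difference, was listed for 2028 events in the authors' deposited table. Of 193 genes with several marked events, 128 had all of them in one direction and 65 in both.

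Of 620 marked retained introns, 320 were higher in Col and 300 in Ler. Alternative 3' sites were higher in Col in 147 of 253 marked events, alternative 5' sites in 83 of 135 and skipped exons in 27 of 46. The direction of no type differed from that of the other types in Fisher's exact test with Benjamini-Hochberg adjustment over 4 types (adjusted p from 0.0674 for retention to 0.651 for skipping). Without events listed at 0 in either ecotype, retention was less often higher in Col than the other types (odds ratio 0.640, adjusted exact p = 0.00459).

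**Figure D1:**
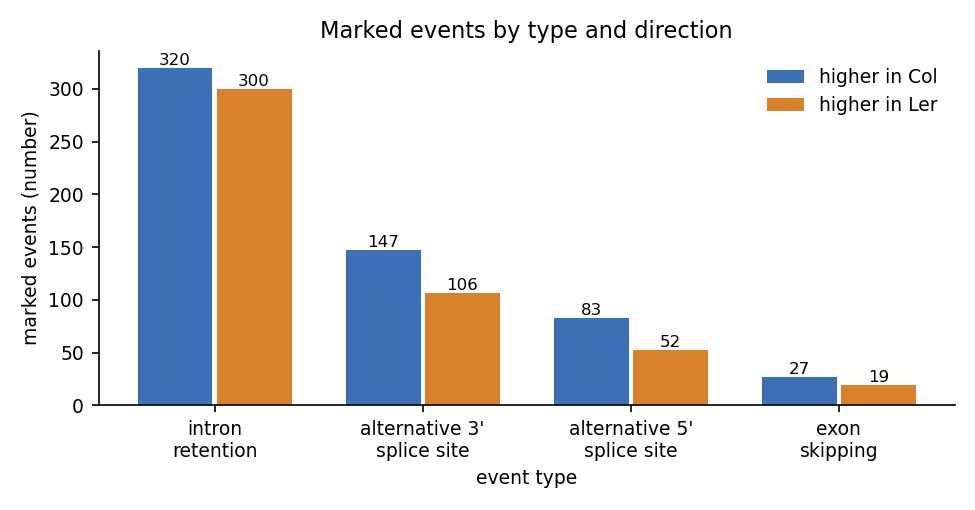
Number of marked events (y axis) per event type (x axis), with blue bars for events with the higher inclusion level in Col and orange bars for those higher in Ler. Retention gave 320 and 300 events, and the 3 other types each had more events higher in Col.

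Introns were marked more often than other events. Of 7399 retained introns 8.38% were marked (7.77 to 9.03%), against 6.44% of the events of other types (odds ratio 1.33, 1.17 to 1.51, Fisher's exact test, adjusted exact p = 5.10e-05). The share was lower for alternative 3' sites, at 6.28% (odds ratio 0.779, adjusted exact p = 0.00149), and for alternative 5' sites, at 6.32% (odds ratio 0.813, adjusted exact p = 0.0381). Skipped exons were marked in 8.06% of events (odds ratio 1.09, adjusted exact p = 0.569). This order depended on the minimum difference: with q under 0.05 alone, the odds ratio was 0.842 for retention (adjusted exact p = 0.000688) and 1.57 for skipped exons (adjusted exact p = 0.000169). Alternative 5' sites no longer passed with q under 0.05 and at least 10 points (odds ratio 0.863, adjusted exact p = 0.132). With 1 event per gene no type passed (adjusted exact p = 0.125 for retention). Exons that lie within an annotated intron were marked in 24 of 188 events (12.8%) and annotated exons in 22 of 383 (5.74%; odds ratio 2.40, 1.25 to 4.63, exact p = 0.00518), but this call ended with q under 0.05 alone (odds ratio 1.36, exact p = 0.154), within events of equal length (1.67, exact p = 0.271) and away from other genes (1.45, exact p = 0.653). A marked retained intron shared an end with a marked event of another type in 107 of 620 cases (17.3%), against 222 of 6779 unmarked ones (3.27%; odds ratio 6.16, 4.76 to 7.93, exact p = 4.18e-38). Events that share an end can rest on the same junction, as in RABG3d and ZML1 below, so joint marking is partly built in. The unmarked group holds all unmarked introns, not only those that share an end with another event. The odds ratio therefore does not show that separate events changed together. Of the 78 marked retained introns that differed by over 50 points, 27 shared an end in this way.

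The events with the largest differences changed almost completely in listed level, and most were at 3' sites. Among the 10 largest marked differences in each direction, 1 event per gene within a direction, 7 of those higher in Ler and 9 of those higher in Col were alternative 3' sites. The differences ranged from 97.2 to 99.7 points, and 18 of these 20 events were listed at 0 in one ecotype. In each direction 4 of the 10 events had another interval length in Ler, and 1 of those higher in Col lacked a coordinate. For these events an offset between the genomes was not ruled out. The 20 events lie in 18 genes, since RABG3d and ZML1 each appear in both directions with the same acceptor. Events higher in Ler with a level listed at 0 in Col included AT5G22210, an aspartyl/glutamyl-tRNA amidotransferase subunit (99.6% in Ler), AT5G46430, a ribosomal protein L32e (99.5%), and PDIL5-1, a protein disulfide isomerase-like protein (99.4%). The included bases of AT5G22210 were 6 bp on the 5' UTR side of the gene, at chromosome 5, 7359528 to 7359533 in TAIR10. Those of AT5G46430 were also 6 bp on the 5' UTR side (chromosome 5, 18833413 to 18833418), and those of PDIL5-1 were 20 bp (chromosome 1, 2467618 to 2467637). The group also held 3' site events of AT1G19650, a Sec14p-like lipid transfer protein (99.0% in Ler), AT5G44580 (98.8%), AT2G23360, a filament-like protein (97.4%), and AT4G25870, a glycosyltransferase family protein (97.2%). In KINESIN-13A, a microtubule motor of the kinesin family, an 80 bp interval on the 5' UTR side had a listed retention level of 99.4% in Ler and 0 in Col (chromosome 3, 5667488 to 5667567). Neither form of this event is annotated. Unmarked 5' site events of the gene were at 99.6% in Col and 6.67% in Ler, and at 96.3% in Col and listed at 0 in Ler. Other junctions of the gene thus also differed, and the listed level alone does not show that the interval is kept in Ler.

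The largest marked difference higher in Col was in AT5G18230, a NOT2/NOT3/NOT5 family transcription regulator, where a 6 bp segment of the coding span was included at 99.9% in Col and 0.187% in Ler (chromosome 5, 6022910 to 6022915). The q value of this event is listed as 0 in the authors' deposited table. In the Col reference, the 20 bases around the acceptor of the longer exon, 10 of the intron and 10 of the exon, read GTTTGTGCAGATGTAGACCA, and those around the acceptor of the shorter exon read GCAGATGTAGACCATGTCAG. ELF9, an RNA-binding protein of the flowering pathway, switched at a 5' site by 9 bp in the coding span (99.4% in Col, listed at 0 in Ler; chromosome 5, 5312124 to 5312132). G-TMT, the gamma-tocopherol methyltransferase of vitamin E synthesis, had a 6 bp segment at 98.4% in Col and listed at 0 in Ler. Its interval had 457 bp in Col and 461 bp in Ler. The others were AT4G38520, a protein phosphatase 2C (99.2% in Col), AT4G18230, an ALG14-like protein (99.1%), AT3G23480, a cyclopropane-fatty-acyl-phospholipid synthase (99.1%), and AT4G22740, a glycine-rich protein (98.6%), all listed at 0 in Ler. The step of AT3G23480 was only 1 bp, and its interval had 1408 bp in Col and 1345 bp in Ler, so an offset between the genomes cannot be told from a switch. In RABG3d, a small GTPase of the Rab family, the 3' site event fell from 99.7% in Col to a level listed at 0 in Ler, while the level listed for the retention event of the adjoining 211 bp interval was 0.334% in Col and 98.9% in Ler. For the 237 bp intron that contains this interval, the listed level was 95.7% in Col and 74.2% in Ler. ZML1, a GATA-type zinc finger protein, had the same pair of events: the 3' site event was at 99.3% in Col and listed at 0 in Ler, and the retention event of the 98 bp interval was listed at 0 in Col and at 98.4% in Ler, with 66.7% and 55.6% for the 113 bp intron that contains it. In both genes the shorter interval is the intron of the inclusion form of the 3' site event, so the pair of levels refers to the same acceptor, and the high level listed for Ler does not show that the interval is kept in the transcript.

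**Figure D2:**
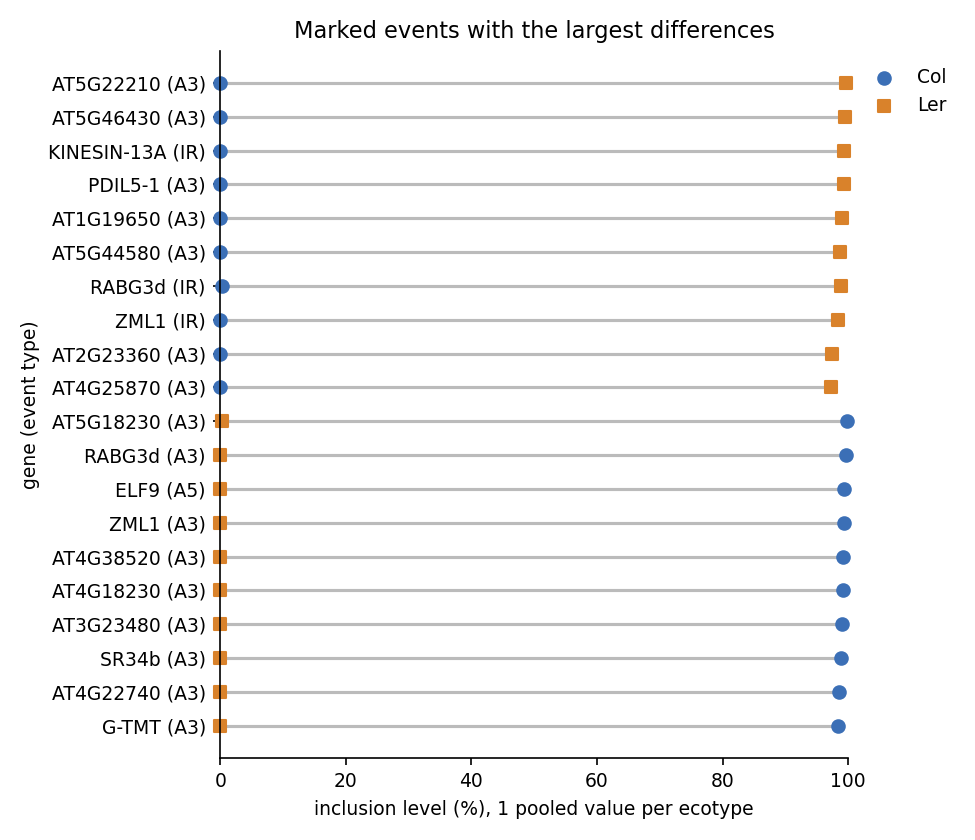
Inclusion level in percent (x axis) of the 10 marked events with the largest differences in each direction (y axis, gene and event type), with a blue circle for the pooled value of Col and an orange square for that of Ler. A3 is an alternative 3' splice site, A5 an alternative 5' splice site and IR a retained intron. The differences lie between 97.2 and 99.7 percentage points.

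Without the requirement of a mark, the 10 largest differences in each direction contained 5 marked events among those higher in Ler and 8 among those higher in Col. Of the others, AT5G42530, AT5G23900, a ribosomal protein L13e, AGD6, an ARF-GAP protein, and CFM3A, a chloroplast CRM-domain protein, were listed at 0 in Col and at 99.0 to 100.0% in Ler. The q value of each of these 4 is 1 in the authors' deposited table. Each lacked a coordinate in one genome. Its segment could not be placed on the Col reference, the genome of the ecotype listed at 0, so these levels alone do not show a switch. AT3G26070, a fibrillin family protein, and AT1G14250, a nucleoside phosphatase, were at 99.6% and 98.6% in Col and listed at 0 in Ler, with a q value of 1 in the authors' deposited table, and AT3G26070 has no interval in Ler in that table. AT1G70620, a cyclin-like protein, was listed at 0 in Col and at 99.2% in Ler without a mark, although its q value is 0.00163 in the authors' deposited table.

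An inclusion level listed at 0 can stand for an including form that was not seen in an ecotype, or for a failed estimate. Of the 61 events that lack a coordinate in one genome, 45 had a level listed at 0. A level of 0 was found in Col alone for 184 events (1.302%, 1.128 to 1.502%) and in Ler alone for 243 (1.719%, 1.518 to 1.947%). This difference passed the exact McNemar test (exact p = 0.00494). Among events with q under 1 the counts were 145 and 187 (exact McNemar p = 0.0243). For retained introns the counts were 16 in Col and 56 in Ler (exact McNemar p = 2.40e-06). Alternative 3' sites gave 112 in each (exact p = 1), alternative 5' sites 53 and 71 (exact p = 0.127), and skipped exons 3 and 4 (exact p = 1). The depth of the ecotypes, which bears on these counts, is unknown.

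SR proteins, the serine/arginine-rich factors that select splice sites, had events in 17 of 20 listed genes, and 3 of the 17 held a marked event. All 8 marked events of the SR genes had the higher inclusion level in Col. SR34b held 5 of them. The first was a 3' site event at 98.9% in Col and listed at 0 in Ler (chromosome 4, 1070046 to 1070057, coding span). A coordinate of this event is missing in Ler, the ecotype listed at 0. Next came another 3' site event at 98.2% and 1.49%, a 5' site event at 98.3% and 12%, and skipping events of overlapping exons at 99.1% and 13.2% and at 98.3% and 15.4%. The SR34b events after the first share a 393 bp excluding interval, so they are not independent. The other marked events were in SR30 and SR34a. SR30 had a 942 bp intron at 28.1% in Col and 14.3% in Ler and a 3' site inside it at 48.8% and 36.7%. Both SR30 events have the same 942 bp excluding interval, so they are not independent either. SR34a had an exon on the 5' UTR side at 28.7% and 17.2%. The remaining 14 SR genes with events had none marked, among them SR34 (intron at 20% in Col and 37.7% in Ler), RSZ22a (36.2% and 52.3%) and RS2Z33 (41.0% and 26.7%).

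Of 14 other splicing factors and RNA-binding proteins with events, 3 were marked. An intron of PTB3, a polypyrimidine tract-binding protein, was retained at 8.01% in Col and 28.1% in Ler. GRP7 had a 143 bp interval listed as retention at 63.2% in Col and 77.6% in Ler and a 5' site event at 18.6% and 8.56%. This interval is the intron of the inclusion form of the 5' site event. Both levels thus refer to the same donor, as for the acceptors of RABG3d and ZML1, and the retention level does not show that the interval is kept. GRP8, a relative of GRP7 named CCR1 in the annotation, had an intron at 42.2% and 30.7%. Unmarked members with larger differences were AT1G60900, a U2AF large subunit (92.9% in Col and 63.2% in Ler), a different 5' site of GRP7 (61.9% and 34.8%) and the RNA-binding protein AtRZ-1c (25% and 52%).

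Among 11 clock genes with events, LUX, a component of the evening complex named PCL1 in the annotation, was marked, with its intron at 45.7% in Col and 65.4% in Ler. This intron had 628 bp in Col and 660 bp in Ler. The clock-related genes XCT (25.8% and 42.9%), RVE8 (34.8% and 50%) and RVE2 (52% and 65.8%) were not marked. Of 8 flowering time genes with events 2 were marked. FLK, an RNA-binding protein that represses FLC, retained a 486 bp intron on the 5' UTR side at 25.9% in Col and 0.851% in Ler (chromosome 3, 1254283 to 1254768), and MAF3, a relative of FLC, had a 3' site event at 47.1% and 64.6%. CO, a central activator of flowering by day length, had an unmarked intron at 68.8% and 50%, and LD an unmarked 3' site event at 80.0% and 62.5%.

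Photosynthesis and chlorophyll genes had events in 19 of 33 members, of which 2 were marked. SAPX, the stromal ascorbate peroxidase, was at 99.9% in Col and 14.5% in Ler in an event listed as retention. Its interval had 0 bp in Col, where the flanking bases adjoin at position 5315469 of chromosome 4, and 80 bp in Ler. The listed value for Col is therefore that of a sequence without this interval. GAPB, a Calvin cycle dehydrogenase, had a marked intron at 88.6% in Col and 65.8% in Ler and an unmarked one at 31.6% and 84.2%. The q value of the unmarked one is 0.0158 in the authors' deposited table, so it is among the events that met both limits without a mark. PORB was at 38.2% and 21.3% and CHLM at 47.7% and 54.8%, both chlorophyll synthesis enzymes and both unmarked. Of 5 NLR immune receptor genes with events 2 were marked, RPS2 and ZAR1. RPS2 had an intron at 86.4% in Col and 67.6% in Ler. ZAR1 had a 6 bp 3' site step at 40.6% and 24.6%, and a 195 bp interval listed as retention at 98.0% and 82.5%. This interval shares its donor with the 228 bp intron of the 3' site event and ends inside it. Its listed level therefore does not show that the interval is kept in the transcript. LAZ5 (68.3% and 79.5%) and AT5G66900 (38.4% and 34.7%) were unmarked. In the list of nonsense-mediated decay, the pathway that removes transcripts with early stop codons, AT1G15280 had a marked 345 bp intron at 25.8% in Col and listed at 0 in Ler. None of the 4 genes with events in the list of loci known as polymorphic between the ecotypes was marked (0 of 4, Wilson upper limit 49.0%). Of these, AOP3, a glucosinolate gene, was listed at 0 in Col and at 81.1% in Ler, HUA2 was at 9.38% and 4.55%, RPP13 at 98.7% and 95.7%, and ER at 13.8% and 12.2%.

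No list passed the test against the other genes with events, of which 13.5% were marked, and lists of 2 to 19 genes with events leave wide intervals. The odds ratios ran from 0, for the polymorphic loci, to 6.41, for nonsense-mediated decay (interval 0.0816 to 504), with adjusted p between 0.787 and 1 (Fisher's exact test, Benjamini-Hochberg over 8 lists), and the smallest unadjusted exact p was 0.138. Stratified by the number of events per gene, all adjusted p were 1. Such strata matter because 6.07% of genes with 1 event were marked, against 24.6% of genes with 3 or more.

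Marked events were more frequent where the genomes differ in length. The interval had another length in Ler than in Col in 2221 events, of which 367 were marked (16.5%, 15.04 to 18.13%), against 679 of 11851 events of equal length (5.73%, 5.33 to 6.16%; odds ratio 3.26, 2.83 to 3.74, Fisher's exact test, exact p = 9.96e-58). The median change was 2 bp, and 939 events changed by 1 bp. The odds ratio was 3.86 for retained introns, 2.87 for alternative 3' sites, 3.48 for alternative 5' sites and 2.13 for skipped exons. Events on the 5' UTR side of genes were marked in 223 of 1978 cases (11.3%), and those of other placed segments in 6.84% (odds ratio 1.73, 1.47 to 2.03, adjusted exact p = 2.21e-10). Within events of equal length this odds ratio was 1.71 (exact p = 5.23e-07). No chromosome differed from the others (adjusted p from 0.417 to 1).

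Short steps between acceptors stood apart among the alternative 3' sites. Those of 3 bp were marked in 67 of 518 events (12.9%, 10.3 to 16.1%), those of other sizes up to 12 bp in 3.67% and those over 12 bp in 6.57%. The odds ratio of 3 bp steps against all other 3' sites was 2.64 (1.93 to 3.57, exact p = 1.59e-09) and within events of equal length 4.18 (exact p = 7.88e-15). In the coding span, 3' site segments that are a multiple of 3 bp were marked in 8.25% of 1212 events and other segments in 3.54% of 1978 (odds ratio 2.45, 1.77 to 3.41, exact p = 2.12e-08). This odds ratio was 1.77 without the 3 bp steps (exact p = 0.00342). At 5' sites the shares were 7.68% and 4.72% (exact p = 0.0277), while for retained introns the odds ratio was 0.918 (0.746 to 1.13, exact p = 0.418).

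**Figure D3:**
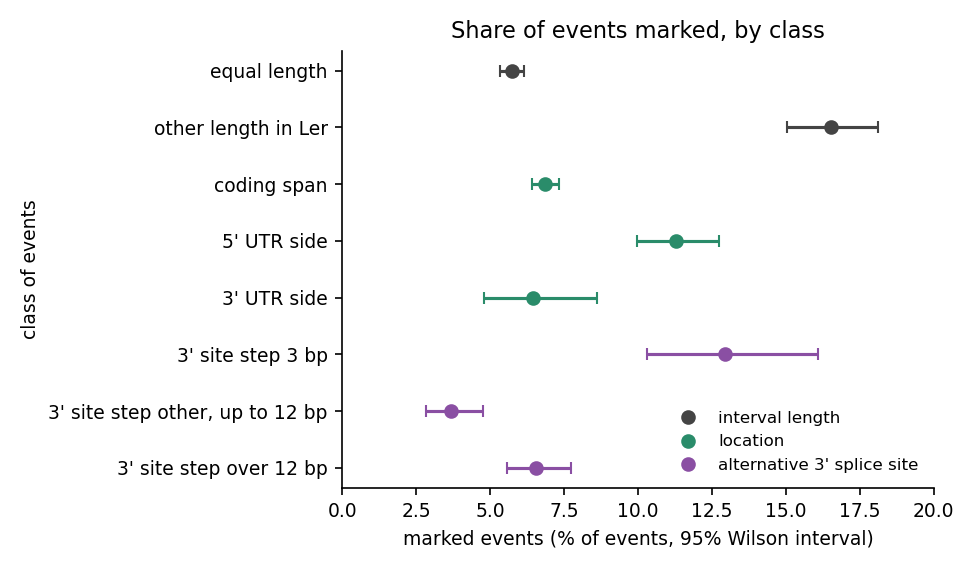
Percent of events marked (x axis) in classes of events (y axis), as points with 95% Wilson intervals, for the length of the interval in Ler, the location in the gene and the step between alternative 3' splice sites. Events of another length in Ler (16.5%), on the 5' UTR side (11.3%) and with a 3 bp step (12.9%) lie above the other classes shown.

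Among alternative splice site events, 49 had exactly 1 junction without GT-AG, GC-AG or AT-AC ends in the Col reference, and 23 of them were marked (46.9%), against 365 of 6089 events with such ends at both junctions (5.99%; odds ratio 13.9, 7.47 to 25.5, Fisher's exact test, exact p = 1.77e-15). In 47 of the 49 the junction without such ends made up at most 10% in Col. TopHat looks for new junctions at such ends, so the classes were not alike in how a junction can be called from Col reads, and the odds ratio holds this difference too. The 23 included the events of AT5G46430, PDIL5-1, AT1G19650, AT2G23360, AT3G23480 and ELF9 described above.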

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

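Planned were the 10 point minimum for counts, types and lists, 1 event per gene for types, lists and levels of 0, 1 event of each type per gene, identical coordinates counted once and the stratified list test. All other alternatives, and every one for interval length, 3 bp steps, in-frame steps, the 5' UTR side, exons within annotated introns and the share higher in Col, were chosen after seeing the data. The 1054 marked events became 2028 with q under 0.05 alone, 594 with at least 20 points, 679 without lost coordinates or another length in Ler and 149 without genes within 500 bp of another gene. The last 3 keep fewer events by construction. With 1 event of each type per gene, 8465 of the events remained. Of 97 alternative values, 70 were classed as unchanged. For tests this means the same direction and side of the threshold, also where a result passed in neither setting. The 70 also include plain counts, which have no direction or threshold.

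With q under 0.05 alone, the odds ratio of marking turned to 0.842 for retention, 1.08 for alternative 3' sites and 1.06 for alternative 5' sites, while skipping rose to 1.57 and exons within annotated introns fell to 1.36. With q under 0.05 and at least 10 points it was 0.863 for alternative 5' sites, which no longer passed, and 0.952 for skipping. With 1 event per gene, which tests fewer events, it was 1.28 for retention, 0.826 for alternative 3' sites, 0.807 for alternative 5' sites and 0 for skipping. Direction in retention became 0.640 without levels of 0. Exons within annotated introns gave 1.67 at equal length and 1.45 away from other genes, and no longer passed in these sets or with q alone; away from other genes the share higher in Col was 50.3%. List odds ratios changed side without passing: clock 1.31, decay 0 and SR proteins 0.815 with 1 event per gene, SR proteins 0.822 when stratified, and polymorphic loci 1.18, other splicing factors 0.966 and photosynthesis 2.59 with q under 0.05 alone. For the other changes the cause was not tested.

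No paired analysis was possible because the table holds 1 pooled value per ecotype and no replicate values. For the same reason leave-one-out sets, a replicate block, other count models, read minimums, pseudocounts, Fisher's test on counts, isoform length scaling, at least 5 supporting reads and detection in both replicates were not run. Depth, which is unknown, limits which differences pass.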

Other observations

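The tests of interval length by quartile, of annotation and of the share higher in Col by distance to other genes were chosen after their results were seen, and that of junction ends after the share of marked events, but before their direction, was seen. Ubiquitin pathway genes were marked in 13 of 63 genes with events (20.6%), ribosomal protein genes in 5 of 70 (7.14%) and transcription factor genes in 5 of 70 (7.14%). DNAJ and heat shock proteins were marked in 0 of 17. Over 16 families fixed by keyword in the annotation, the smallest adjusted p was 0.625 (Fisher's exact test, Benjamini-Hochberg). The smallest unadjusted Fisher p was 0.0966, so no family passed. A keyword can catch genes of another kind: SOS4, a pfkB-like carbohydrate kinase, counted among the protein kinases. The marked events of transcription factors were higher in Ler in 12 cases and in Col in 2, but lay in only 5 genes. Those of the keyword family of RNA-binding (RRM) proteins were higher in Col in 16 cases, 5 of them in SR34b, and in Ler in 2, over 13 genes. Neither direction was tested. Examples were AT3G61420, with an intron at 6.49% in Col and 97.5% in Ler, PAT1, a GRAS family regulator, with a 5' site event at 46.3% and 98.2%, and LARP6a, an RNA-binding protein, with a 5' site event at 97.4% and 28.6%. Neighbouring genes were both marked in 113 pairs against a mean of 95.9 in shuffles (one-sided permutation p = 0.0248). Without genes within 500 bp of another gene of the table it was 78 pairs against 71.7 (one-sided permutation p = 0.212). Neighbours here are consecutive genes among those with events, so genes without events can lie between them.

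The marked alternative sites without common junction ends in the Col reference all went one way. In 23 of 23 such events (100%) the junction without GT-AG, GC-AG or AT-AC ends in Col was the one used more in Ler, but this outcome was close to fixed, since TopHat looks for new junctions at such ends and the junction made up at most 10% in Col in 47 of all 49 events. The direction therefore cannot tell whether the candidate explanation, splice sites that exist in Ler but not in Col, holds, and it stays open. Examples beyond the largest differences are TBL14 (listed at 0 in Col and 96.2% in Ler), AT3G02290 (95.8% in Ler) and SYP41 (43.5% in Ler). The Ler sequence was not used here, so the base changes themselves were not seen.

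Events of another length in Ler were marked more often, and 3 technical explanations were set against this. Loss of reads over insertions or deletions would lower inclusion in Ler, but marked introns of another length were higher in Col in 50.7% of cases and those of equal length in 51.9% (odds ratio 0.954, 0.672 to 1.36). Longer intervals, which hold more insertions and deletions, do not account for the whole excess, since the smallest odds ratio within quartiles of length was 2.53 (1.94 to 3.28). Divergence of the whole gene is not the whole cause either, since events of another length were marked more often than equal-length events of the same genes (odds ratio 2.01, 1.62 to 2.50), although the latter were marked in 8.97% of cases against 5.28% in other genes. A hypothesis that stays open is that the length changes, or base changes near them, may alter splicing in Ler, and alignment errors that go both ways could also do so.

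More marked events had the higher inclusion level in Col (54.7%, against 51.1% of unmarked events), but not the 149 outside genes within 500 bp of another gene (50.3%, 42.4 to 58.3%, against 55.5% of the other marked events, exact p = 0.249), so whether the excess arises because overlapping or adjoining genes share reads cannot be told from these values. Levels listed at 0 were not the cause, as 54.8% (51.6 to 58.0%) of the 938 events above 0 in both ecotypes were higher in Col. Where exactly 1 form is annotated, that form was higher in Col in 384 of 562 marked events (68.3%), but the annotated form was the excluding one in 379 of the 562, where inclusion was higher in Col in 39.3%, and the including form in 183, where it was higher in Col in 84.2%. An even preference for the annotated form would give a higher inclusion level in Col in 43.6% (42.3 to 45.0%) of the 562 events, against 53.9% observed (49.8 to 58.0%), so it works against the excess, and events with both forms annotated also had the higher level in Col in 56.2% of 361 cases (51.1 to 61.3%). A preference that is stronger for including forms, a difference between the ecotypes themselves and one in depth stay open and were not tested.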
